A study of Lactiplantibacillus plantarum with 4 samples.

How the data were processed

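RNA of 4 Lactiplantibacillus plantarum WCFS1 strains was compared on 4 two-colour arrays, each with a Cy3 and a Cy5 target. Per the labels, array 1 set the strain labelled trxB1 mutant (Cy5) against the wild type (WT, Cy3), array 2 the trxB1 overexpression strain (Cy5) against the strain labelled trxB1 mutant (Cy3), array 3 the strain labelled trxB2 mutant (Cy5) against the overexpression strain (Cy3), and array 4 the WT (Cy5) against the strain labelled trxB2 mutant (Cy3). The arrays close a loop in which every strain was hybridised on 2 arrays, with the dyes exchanged. No strain pair was repeated, and nothing in the labels says whether the targets of a strain came from separate cultures. The SEs and p-values below measure only how far the log ratios fail to add up around this loop, a spread which may be technical.

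Per the labels' design text, the arrays were a custom 11K 60-mer design with about 3 probes per transcript, scanned in a ScanArray Express, and the authors corrected the background in BASE and analysed the ratios with limma at an FDR of 1% and 1.5-fold. Per the file headers, spots were quantified with ImaGene 7.5.0, and the deposited scanner files give the mean intensity of each spot with its local background on a linear scale, not normalized. The spot quality marks and the mark for saturated spots in the deposited files are codes, not intensities, and are other columns of the same files. The deposited value table holds the authors' processed log2 ratios for 8850 spots per array. Its scale and direction are not stated, so it was set against the scanner values. Its rows followed the spot order of the scanner files. Its columns ran with a slope of -1.06 on the normalized log2 Cy5/Cy3 values of their own array, and correlated with them between -0.995 and -0.993, so the table runs as log2 Cy3/Cy5 on nearly the same scale. Its medians were -0.00078, 0.0033, -0.006 and -0.0054 for arrays 1 to 4. The design text defines the ratio the other way, and names Cy3 as the wild type, which the dyes in the labels bear out for array 1 but not for the other arrays. The dyes in the labels set every direction used here.

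Each array held 10807 spots, of which 544 were controls and 10221 carried a locus tag in the probe ID. The tags named 3092 loci, with a median of 3 probes each. Intensities were background corrected with normexp (offset 50), normalized by loess within each array with control and marked spots at weight 0, and turned into log2 Cy5/Cy3. Control spots and spots marked empty or poor were left out (376 to 485 spots per array). Spots of a probe were averaged, then probes of a locus. The 3059 loci with a value on all 4 arrays were fitted in limma 3.58.1 (R 4.3.3; lmFit and eBayes) with a loop model of 3 strain differences and no dye term. A locus was called at a Benjamini-Hochberg FDR under 0.01 and a change of at least 1.5-fold. In all 6 comparisons every locus with a change of at least 1.5-fold also passed the FDR. The fold minimum alone therefore set the calls. The model leaves 1 residual degree of freedom per locus, the sum of the 4 log ratios around the loop, which holds dye effects and error. The median size of that sum was 0.108 and its 95th percentile 0.321. The prior degrees of freedom were 24.8. Each SE and p-value therefore rests mostly on the spread common to all loci and little on that of the locus itself. Since the dye direction is that residual, fitted differences are the same with a dye term.

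Image names in the headers put arrays 1 and 2 on 1 slide (slide 1) and arrays 3 and 4 on another (slide 2). A dye effect of opposite sign on the slides has the form of a strain difference in this loop, so slide could not be fitted as a block. The difference between the overexpression strain and the WT was instead computed within each slide, and each of the other comparisons was also computed along the 2 paths round the loop, which have no array in common.

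The files do not pair locus tags with gene symbols. The gene table given for the value table's probes lists 955 probes, each with 1 symbol, and 304 of its 330 symbols have several probes. Its probe numbers were set against the array's spots in 10 orders, and 0 of those 304 symbols had all their probes on 1 locus tag in any of them, so the table was not used. The reference gene table (assembly ASM991365v1, 3031 genes of another strain) held 0 of the 3092 locus tags. Locus tags are therefore printed without names, at most 2 that rose and 2 that fell per comparison. The exceptions are lp_0761 (trxB1), lp_2585 (trxB2), lp_2323 (tpx), lp_3578 (kat), lp_0727 (groES) and lp_0728 (groEL), whose tags were set from general knowledge of the WCFS1 annotation before the data were examined and are not paired with names in the files. Of 23 gene lists set then, 19 needed symbols or products and have no member here, 2 had fewer than 3 members, and 2 were tested: the thioredoxin system (3 members) and the native plasmids (44 members). The plasmid list had been set for another form of ID that no probe here carries, and the IDs that start lp_p1, lp_p2 or lp_p3 were taken in its place after the IDs had been seen. List shifts were tested with cameraPR on limma's moderated statistics at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over both lists within a comparison, and with camera at an estimated correlation beside it. That estimate rests on 1 residual degree of freedom and came out at -0.333 for the thioredoxin system and -0.021 for the native plasmids in every comparison. The test with it is read on the same 1 degree of freedom. A call lost there is therefore not shown to rest on correlated loci.

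The loci named in each comparison are trxB1 and trxB2, and the 2 largest rises and 2 largest falls among called loci with at least 2 probes measured on all arrays, all of the same sign. The rule set beforehand took longer lists, which were shortened because the loci have no names here. Further loci that were chosen after their values were seen are named as such. Fold changes of comparisons that share the WT were related across loci beside 100 simulations without strain effects. Locus tags were put in numerical order, and called loci with a neighbour called the same way were counted beside 100000 shuffles of the calls.

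The scripts were tested on simulated data. In 3059 simulated loci, 50 of 50 loci changed 1.8-fold were recovered in each of the 3 comparisons with the WT, as were 50 of 50 changed 2-fold and 50 of 50 changed 3-fold. Of the loci changed 1.2-fold, 0 of 50 passed the fold minimum, and 0 of 2859 unchanged loci were called. The simulated errors were independent and of the fitted size, without probe disagreement, marked spots, normalization or differences between cultures. These counts test the scripts and do not give the rate of false calls in these data. Of 200 random lists of unchanged loci in each of these comparisons, 0 had a list p under 0.05. As the simulated loci were independent, this leaves open how the list test behaves where loci move together. Alternatives planned before the data were examined covered background correction, normalization, the spot summary, probe averaging, dim and marked spots, the value table, the moderation, thresholds, each array left out and a dye term. Alternatives chosen after seeing the data were the probe series of the value table, probes measured on all 4 arrays, separate channels without a dye term, and 1 relation between single arrays.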

Results

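Transcript levels of 4 strains of the lactic acid bacterium Lactiplantibacillus plantarum WCFS1 were compared: the WT, a strain labelled trxB1 mutant, a strain that overexpresses trxB1 and a strain labelled trxB2 mutant. Thioredoxin reductases such as the products of these genes use NADPH to reduce thioredoxin, which in turn reduces disulfide bonds in proteins. The 4 arrays formed a loop in which each array compared 2 strains and each group of arrays held 1 array. The median spot signal ran from 1003 to 1360 over the 8 channels, against a median local background of 482 to 496. Between 96.9% and 99.2% of the spots with a locus tag lay above the background mean by more than 2 background SD, and each channel had 2 to 13 saturated spots. The number of arrays limits the precision. No comparison had a replicate array, and each log2 difference below is the loop estimate ± SE from limma over the 4 arrays, with the first-named strain over the second. The SE comes mostly from all loci together and can be too small for a locus whose arrays disagree. Directions follow the dyes in the labels and are opposite to those of the deposited value table.

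The targeted genes were examined first. The trxB1 locus, lp_0761, was higher in the overexpression strain than in the WT by 1.85 ± 0.094 on the log2 scale, a 3.62-fold rise (limma adjusted p = 3.7e-14). In the strain labelled trxB1 mutant it was not lower than in the WT: its log2 difference was 0.37 ± 0.082, short of the 1.5-fold minimum, and the 4 spots of its 3 probes were above the WT on array 1, by 0.13 to 0.29. In the strain labelled trxB2 mutant, lp_0761 differed from the WT by -0.47 ± 0.082, also short of the 1.5-fold minimum, and its probes disagreed. Probe 3 gave -1.0 ± 0.095 there (limma adjusted p = 6.5e-05), probe 2 gave 0.42 ± 0.13 and probe 1 gave -0.11 ± 0.11. In the overexpression strain the 3 probes gave 1.36, 1.24 and 1.51. Probes 1 and 2 were marked poor on array 3, so the locus mean rests there on probe 3 alone, but on all 3 probes elsewhere. These probe values include the marked spots. The locus values of 1.85 and 0.37 lie above all 3 probe values in their strains, and the change of probes between arrays enters them. With the marked spots kept, the locus means were 1.37 for the overexpression strain, 0.13 for the strain labelled trxB1 mutant and -0.23 for the strain labelled trxB2 mutant. With probe 3 alone, the only one measured on all 4 arrays, the values were 1.51, 0.13 and -1.0 in the same order. In the main fit without array 1 the value for the strain labelled trxB1 mutant was 0.78. Without array 4 that for the strain labelled trxB2 mutant was -0.89. The change of probes on array 3 enters both of these values.

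The trxB2 locus, lp_2585, was not called in any strain. Its log2 differences from the WT were -0.07 ± 0.067 in the strain labelled trxB2 mutant, -0.15 ± 0.078 in the overexpression strain and -0.13 ± 0.067 in the strain labelled trxB1 mutant. Its probes disagreed, with 0.30 ± 0.099, -0.14 ± 0.093 and -0.37 ± 0.092 in the strain labelled trxB2 mutant, and 0.17 ± 0.11, 0.11 ± 0.11 and -0.71 ± 0.11 in the overexpression strain, the last at a limma adjusted p of 0.0024. The level of lp_0761 goes with the overexpression label under the dyes as named, and goes against the trxB1 mutant label. A probe outside a disrupted part checks nothing, and the positions of the probes in the genes are not given in the sources used here. Both mutant strains are named by their labels throughout, and every direction that involves them rests on those labels.

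**Figure D1:**
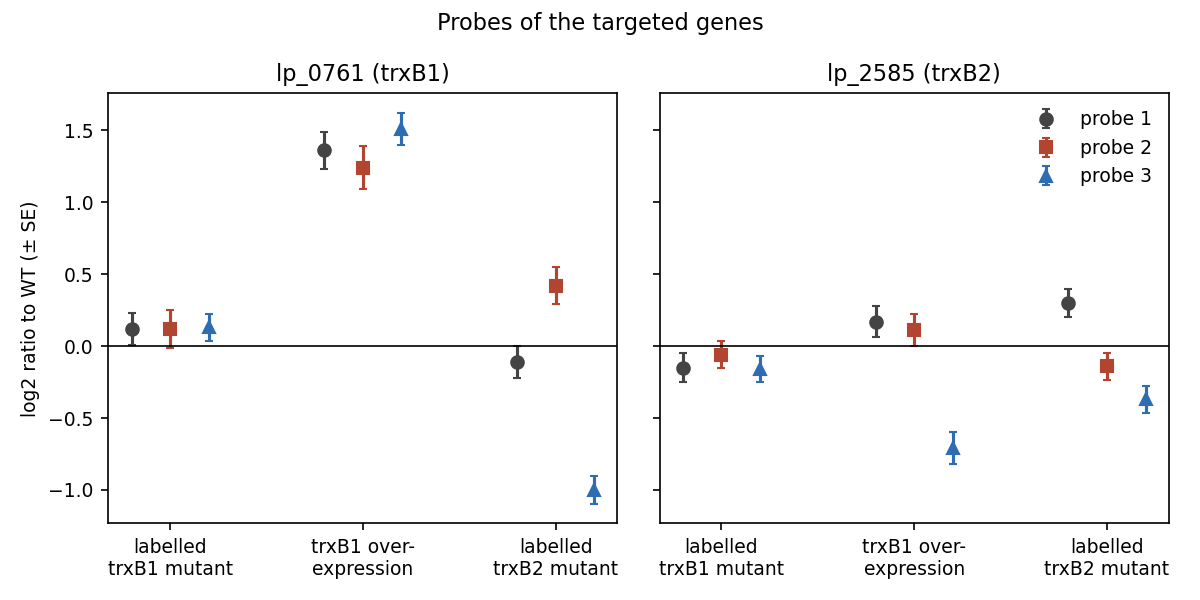
Log2 ratio to the WT (± SE, limma, 4 arrays) of the 3 probes of lp_0761 (trxB1, left) and of lp_2585 (trxB2, right) in each strain on the horizontal axis, with marked spots included. The 3 probes of lp_0761 lie between 1.24 and 1.51 in the overexpression strain, between 0.12 and 0.13 in the strain labelled trxB1 mutant, and between -1.0 and 0.42 in the strain labelled trxB2 mutant.

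The strain labelled trxB1 mutant differed from the WT at 47 of 3059 loci, of which 6 rose and 41 fell. The largest rises were lp_1163, by 0.89 ± 0.067 on the log2 scale or 1.85-fold (limma adjusted p = 1.1e-10), and lp_3045, at 0.74 ± 0.068. The largest falls were lp_2034, at -1.40 ± 0.068 or 2.65-fold, and lp_0183, at -1.40 ± 0.07. The locus lp_2034 belonged to a run of 6 consecutive locus tags that all fell, with a mean of -0.99. Of the 43 called chromosomal loci, 17 had a neighbouring tag called the same way, against a mean of 0.91 in shuffled calls (permutation p = 1e-05, the smallest that 100000 shuffles give). Array 1 alone and the other 3 arrays together each give this difference. Both estimates reached 1.5-fold in the called direction at 36 of the 47 loci and correlated across all loci at r = 0.67 (loci are not independent replicates). Loci were called on a weighted mean of both estimates, so agreement at called loci is partly built in. The same holds for the comparisons below. Without background correction 24 loci were called, and at an FDR of 0.05 with no fold minimum 639 were. The share of rises among the calls was 12.8%, against 25.0% without background correction and 44% with no fold minimum.

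The overexpression strain differed from the WT at 97 loci, 22 of them higher and 75 lower. Apart from trxB1 itself, the largest rises were 2 loci whose IDs place them on the native plasmid numbered 2, lp_p2_02 at 2.28 ± 0.082 or 4.86-fold (limma adjusted p = 3.0e-17) and lp_p2_03 at 1.85 ± 0.081 or 3.60-fold. The largest falls were lp_RNA01, at -1.41 ± 0.082 or 2.65-fold, and lp_1594, at -1.30 ± 0.077 or 2.46-fold, which was 1 of 2 adjoining tags that fell. Of 88 called chromosomal loci, 20 had a neighbour called the same way, against 3.46 in shuffled calls (permutation p = 2e-05). Within slide 1, lp_p2_02 differed by 2.14, lp_p2_03 by 1.73, lp_RNA01 by -1.27 and lp_1594 by -1.27. Within slide 2 the values were 2.42, 1.97, -1.54 and -1.32. Of the 97 called loci, 58 reached 1.5-fold within both slides, and the 2 estimates correlated across loci at r = 0.83. Without background correction 42 loci were called, and at an FDR of 0.05 with no fold minimum 1294 were, 47.8% of them higher against 22.7%.

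The strain labelled trxB2 mutant differed from the WT at 134 loci, 34 of them higher and 100 lower. The neighbouring loci lp_1229 and lp_1230 rose the most, by 1.63 ± 0.067 or 3.10-fold (limma adjusted p = 3.6e-16) and by 1.25 ± 0.067 or 2.37-fold, within a run of 4 consecutive tags that rose with a mean of 1.11. The largest falls were lp_0577, at -1.86 ± 0.067 or 3.63-fold, in a run of 3 tags with a mean of -1.31, and lp_RNA01, at -1.52 ± 0.071 or 2.88-fold. Of 127 called chromosomal loci, 34 had a neighbour called the same way, against 6.38 in shuffled calls (permutation p = 1e-05, the smallest that 100000 shuffles give). Array 4 alone and the other 3 arrays both gave 1.5-fold at 93 of the 134 loci, with r = 0.83 across loci. Without background correction 61 loci were called, and at an FDR of 0.05 with no fold minimum 1358 were, 49.3% of them higher against 25.4%.

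**Figure D2:**
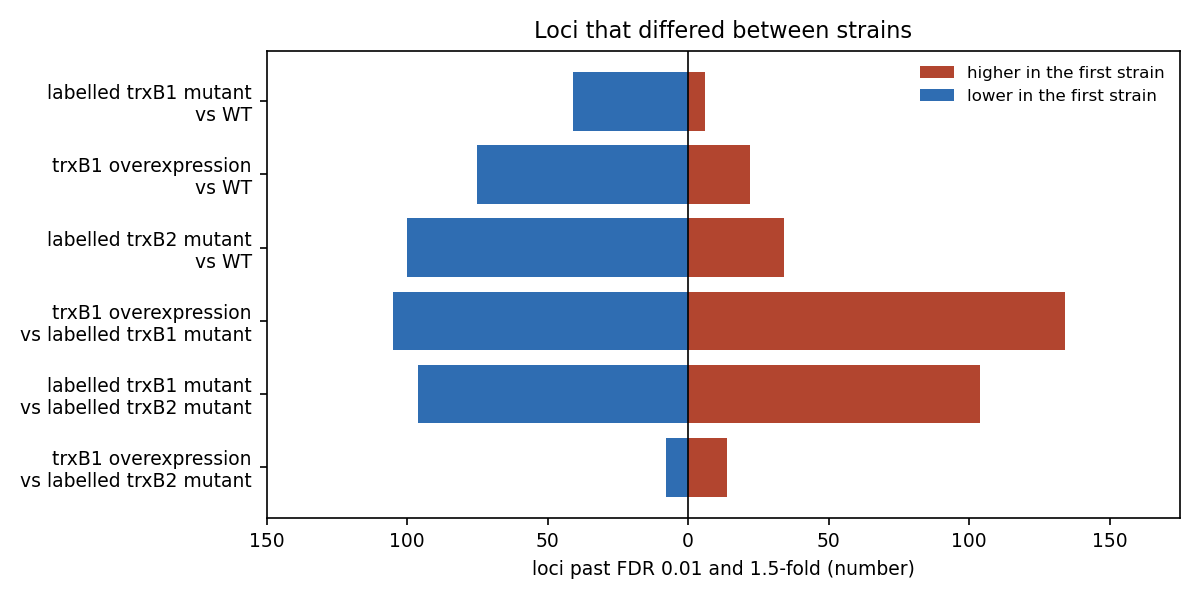
Number of loci past an FDR of 0.01 and 1.5-fold in each of the 6 comparisons, with loci higher in the first-named strain to the right of 0 and loci lower in it to the left. The comparison of the overexpression strain with the strain labelled trxB1 mutant has 134 higher and 105 lower loci, and that of the overexpression strain with the strain labelled trxB2 mutant has 14 and 8.

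Between the overexpression strain and the strain labelled trxB1 mutant, which by their labels change the same gene in opposite ways, 239 loci differed. Of these, 134 were higher in the overexpression strain and 105 lower. The plasmid loci lp_p2_02 and lp_p2_01 had the largest rises, 2.72 ± 0.071 or 6.58-fold (limma adjusted p = 9.5e-21) and 2.12 ± 0.068 or 4.35-fold. The largest falls were lp_1594, at -1.40 ± 0.067, and lp_1597, at -1.34 ± 0.068, the latter in a run of 3 tags with a mean of -1.09. The trxB1 locus lp_0761 was higher by 1.49 ± 0.082 or 2.80-fold, while lp_2585 differed by -0.02 ± 0.067. With the marked spots kept, lp_0761 was higher by 1.24 ± 0.075 or 2.37-fold. Calls formed 10 runs of 3 or more consecutive tags, the longest of 7 loci that rose with a mean of 0.84, and 87 of 228 called chromosomal loci had a neighbour called the same way, against 17.0 in shuffled calls. Array 2 alone and the other 3 arrays both gave 1.5-fold at 174 of the 239 loci, with r = 0.91 across loci, and without array 2 the loci with a change of at least 1.5-fold numbered 376 against 239 with all arrays. Without background correction 93 loci were called, 39.8% of them higher against 56.1%, and at an FDR of 0.05 with no fold minimum 1850 were.

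The strains labelled trxB1 mutant and trxB2 mutant differed from each other at 200 loci, 104 of them higher in the strain labelled trxB1 mutant. There, lp_0577 was higher by 1.76 ± 0.077 or 3.38-fold (limma adjusted p = 2.2e-15) and lp_1597 by 1.58 ± 0.079. The loci lp_1229, at -1.87 ± 0.077, and lp_2037, at -1.43 ± 0.077, were the furthest below, in runs of 4 and 5 tags. The trxB1 locus lp_0761 was higher in the strain labelled trxB1 mutant by 0.84 ± 0.094 or 1.79-fold, a call that was lost with marked spots kept, at 0.35 ± 0.087. Estimates through the WT and through the overexpression strain both gave 1.5-fold at 145 of the 200 loci, with r = 0.88 across loci. Without background correction 95 loci were called, and at an FDR of 0.05 with no fold minimum 1477 were.

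The overexpression strain and the strain labelled trxB2 mutant differed at 22 loci, the fewest of the 6 comparisons, with 14 higher and 8 lower in the overexpression strain. The rises were led by the plasmid locus lp_p2_02, by 2.40 ± 0.071 or 5.26-fold (limma adjusted p = 2.3e-19), by lp_0761, at 2.33 ± 0.082 or 5.02-fold, and by lp_p2_03, at 1.93 ± 0.07. With the marked spots kept, lp_0761 was higher by 1.60 ± 0.075 or 3.02-fold. The loci lp_1230, at -1.14 ± 0.067, and lp_1229, at -1.03 ± 0.067, fell the most. Array 3 alone and the other 3 arrays both gave 1.5-fold at 14 of the 22 loci, with r = 0.66 across loci, and without array 3 the loci with a change of at least 1.5-fold numbered 35 against 22 with all arrays. Without background correction 10 loci were called, and at an FDR of 0.05 with no fold minimum 729 were. The share of rises, 63.6%, was 75.0% with median centring in place of loess and 45.5% in the deposited value table. That table holds 1 probe series and gave 2851 loci. With the probes of that series alone, processed as in the main fit, the share was 52.9%.

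Of the native plasmid loci, 5 of 44 rose in the overexpression strain against the WT and 0 fell, and the counts were the same when adjusted over the list alone. The list shifted upward with a median of 0.265 (adjusted p = 1.91e-15 with the preset correlation), a call that was lost at adjusted p = 0.154 with an estimated correlation, read on 1 degree of freedom. All 3 loci of plasmid 2 rose, with a median of 1.85, while 1 of the 3 loci of plasmid 1 and 1 of the 38 loci of plasmid 3 did, with medians of 0.12 and 0.25. In the strain labelled trxB2 mutant 0 of the 44 were called and the 3 loci of plasmid 2 lay between -0.14 and -0.08. In the strain labelled trxB1 mutant 0 of the 44 were called, with a list median of -0.081 (adjusted p = 0.0182 with the preset correlation and 0.334 with an estimated correlation). The loci of plasmid 2 stood there at -0.51, -0.44 and -0.20 (limma adjusted p = 2.9e-06, 4.9e-05 and 0.04), short of 1.5-fold. Against the strain labelled trxB1 mutant, 10 of the 44 rose in the overexpression strain (adjusted p = 1.65e-14, and 0.161 with an estimated correlation). Against the strain labelled trxB2 mutant, 4 of them rose there (adjusted p = 7.1e-28, and 0.121 with an estimated correlation), and between both mutant strains 1 of the 44 fell in the strain labelled trxB1 mutant (adjusted p = 0.144).

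The thioredoxin system list held trxB1, trxB2 and tpx, a thiol peroxidase that takes electrons from thioredoxin. In the overexpression strain against the WT, 1 of its 3 members rose, trxB1, also when adjusted over the list alone, while tpx (lp_2323) stood at -0.14 ± 0.078. The list's test was upward (adjusted p = 0.00525, and 0.46 with an estimated correlation), although its median was -0.136 and its mean 0.524, so that median and test differed in sign. It also passed against the strain labelled trxB1 mutant (adjusted p = 0.0315, and 0.386 with an estimated correlation) and against the strain labelled trxB2 mutant (adjusted p = 2.76e-08, and 0.287 with an estimated correlation), in each with trxB1 as the only member called. As the list holds the overexpressed gene itself, its passes in the overexpression strain say nothing of the other members. The list did not pass in the strain labelled trxB1 mutant (adjusted p = 0.937) or the strain labelled trxB2 mutant (adjusted p = 0.572) against the WT, nor between these strains (adjusted p = 0.334). The catalase gene kat (lp_3578) stood at 0.50 ± 0.081 in the overexpression strain, 0.23 ± 0.07 in the strain labelled trxB2 mutant and -0.05 ± 0.07 in the strain labelled trxB1 mutant, all under the 1.5-fold minimum, and its change in the overexpression strain had a limma adjusted p of 2.5e-05. The chaperonin genes groES (lp_0727) and groEL (lp_0728) stood at -0.28 ± 0.083 and -0.33 ± 0.081 in the overexpression strain, at 0.12 ± 0.072 and -0.14 ± 0.07 in the strain labelled trxB2 mutant and at -0.19 ± 0.072 and -0.11 ± 0.07 in the strain labelled trxB1 mutant. None of these 6 values was called, and 0 of the 3 groES probes were measured on all 4 arrays. With an array left out, groES ran from -0.43 to -0.12, 0.04 to 0.34 and -0.42 to -0.12 in these strains, groEL from -0.46 to -0.20, -0.21 to 0.05 and -0.30 to -0.04, and kat from 0.39 to 0.62, 0.18 to 0.41 and -0.22 to 0.01.

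Changes against the WT in the overexpression strain and in the strain labelled trxB2 mutant ran together across loci, with r = 0.76 and rho = 0.76, against a mean r of 0.58 in 100 simulations without strain effects that share the WT channels. The covariance was 0.0568 against a simulated 0.00311. Of their calls, 60 loci fell in both strains, against 2.5 for independent lists, 3 rose in both, against 0.24, and 0 moved in opposite directions. The strain labelled trxB1 mutant had r = -0.08 with the overexpression strain, against a simulated mean of 0.58, with a covariance of -0.00425 against a simulated 0.00313. With the strain labelled trxB2 mutant it had r = 0.08, against a simulated mean of 0.33, and a covariance of 0.00429 against 0.00156. It shared 8 falls with the overexpression strain, against 1 for independent lists, with 1 shared rise and 1 locus called in opposite directions, and 12 with the strain labelled trxB2 mutant, against 1.3. Without array 1, the correlation with the overexpression strain became 0.22 and that with the strain labelled trxB2 mutant 0.23. The simulations hold array error alone, so their r is not the value expected where strains also differ. Between the 2 mutant strains, r lay under the simulated mean while the covariance lay above it. Part of the excess of shared calls may come from the shared WT channels. Arrays 2 and 4, which share no strain, were correlated at r = 0.55 once array 4 was turned to read the strain labelled trxB2 mutant over the WT. Arrays 1 and 3, which also share no strain and read the strain labelled trxB1 mutant over the WT and the strain labelled trxB2 mutant over the overexpression strain, were correlated at r = 0.32. In simulations without strain effects neither relation exceeded 0.05.

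**Figure D3:**
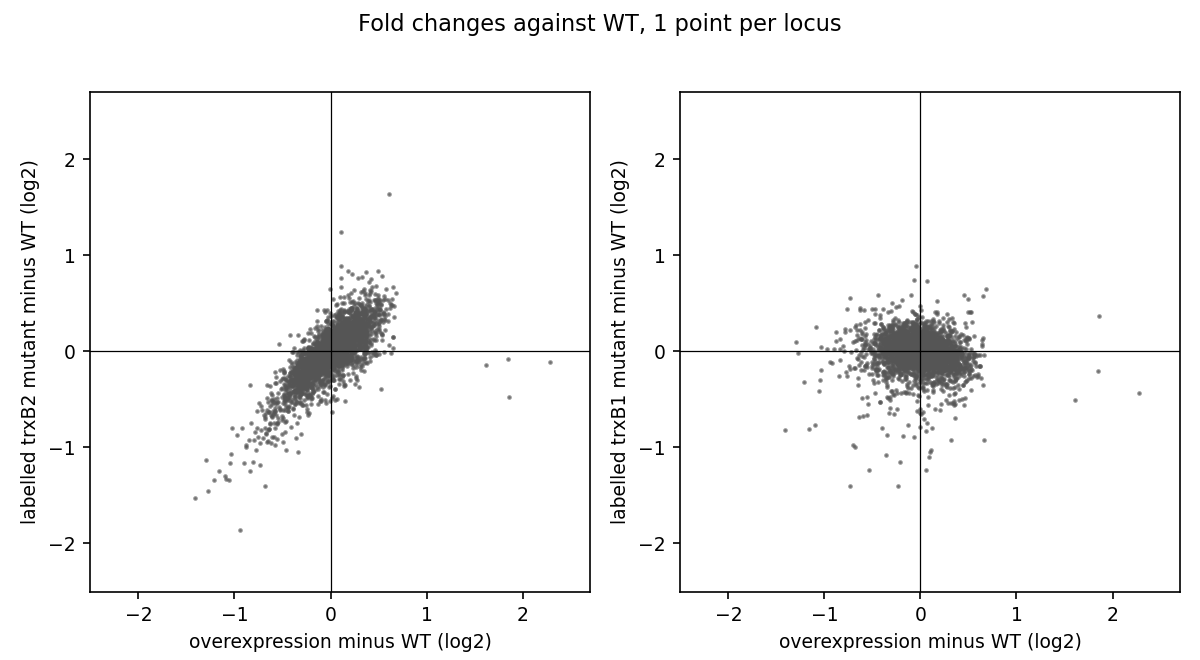
Log2 change against the WT of the 3059 loci, 1 point each, in the overexpression strain (horizontal axis, both panels) and in the strain labelled trxB2 mutant (left) or trxB1 mutant (right, vertical axes). The points on the left follow the diagonal at r = 0.76, those on the right do not, at r = -0.08.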

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

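Signals outside the loci compared above were seen in spots whose probe IDs carry no locus tag. They were counted against the 79 negative control spots after the values were seen. Of 36 spots with IDs that start mtf, 29 exceeded the highest negative control in all 8 channels, with a median signal of 1242 over the group against 524.5 for the negative controls. All 3 spots with SRP in their IDs did so, with a median of 1627, and 0 of 3 spots with anti in their ID. The SRP spots lay above the WT by 0.51, 0.69 and 0.91 on the log2 scale in the overexpression strain, by 0.58, 0.79 and 0.80 in the strain labelled trxB2 mutant, and at -0.34, -0.18 and -0.10 in the strain labelled trxB1 mutant. What these IDs stand for is not given in the sources used here, and no explanation was tested.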

How the results depend on the processing

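The probes measured on all 4 arrays, the value table's probe series, separate channels without a dye term and the slide 1 relation were chosen after seeing the data. The planned fit of separate channels with a dye term was not run, since it leaves no residual degree of freedom among log ratios. The 6 counts stayed within 1.5 times of the reported ones in every setting with a test except 2. Without background correction, they were 24 for the strain labelled trxB1 mutant against the WT, 42 for the overexpression strain against the WT, 61 for the strain labelled trxB2 mutant against the WT, 93 for the overexpression strain against the strain labelled trxB1 mutant, 95 between the mutant strains and 10 for the overexpression strain against the strain labelled trxB2 mutant. At an FDR of 0.05 with no fold minimum, a looser threshold, they were 639, 1294, 1358, 1850, 1477 and 729. Leaving out each array in turn leaves no test: loci of at least 1.5-fold then numbered 211 to 376 for the overexpression strain against the strain labelled trxB1 mutant and 30 to 35 against the strain labelled trxB2 mutant, with 51 to 65, 80 to 141, 140 to 141 and 195 to 265 in the others. The trxB1 level against the WT ranged from 0.23 to 0.78, 1.58 to 2.13 and -0.89 to -0.34 in the strain labelled trxB1 mutant, the overexpression strain and the strain labelled trxB2 mutant. The change of its probes on array 3 enters these ranges. With 1 fit per probe, which asks for 2 passing probes where trxB1 has 1 probe measured on all arrays, its rise of 1.51 in the overexpression strain was not called. Its values of 0.37 and -0.47 in the mutant strains passed without the fold minimum, and the latter was -1.0 and called with probes measured on all 4 arrays. The trxB2 level in the overexpression strain was 0.11 with 1 fit per probe. Of 1118 further values for 20 named loci in 54 pairs of locus and comparison, 20 changed sign, 0 of them in a called pair. Of these, 9 came with an array left out, for lp_3578, lp_0728 and lp_2323, and 11 in other settings: lp_2585 in the overexpression strain against the strain labelled trxB1 mutant gave 0.05 without background correction, 0.03 with median centring, 0.04 with the median of probes and 0.17 per probe, and 0.02 against the strain labelled trxB2 mutant without background correction. It gave 0.09 per probe between the mutant strains, where lp_0728 gave 0 with median centring, -0.03 with spot medians, -0.05 with the median of probes and -0.06 per probe, and lp_0727 in the overexpression strain against the strain labelled trxB1 mutant gave 0.10 with median centring. Of 563 values for the 27 called pairs (15 loci), 6 lost the call, all of them trxB1. Only values with an array left out or a dye term were compared with the spread, and 33 moved by more. The other 524 either moved by less in that comparison or, in the other settings, kept the call and sign whatever the size of the move. For example, lp_p2_03 in the overexpression strain against the WT kept its call at 0.9 without background correction, against 1.85 in the main fit. The list calls were all lost with an estimated correlation: adjusted p was 0.334, 0.154, 0.161 and 0.121 for the native plasmids and 0.46, 0.386 and 0.287 for the thioredoxin system. Both that estimate and its test rest on 1 residual degree of freedom, where even a strong shift gives a large p. The loss therefore cannot be laid to correlation between loci. The native plasmid shift in the strain labelled trxB1 mutant was also lost with median centring (adjusted p = 0.0763) and without background correction (adjusted p = 0.104), and the thioredoxin list turned downward there with median centring (adjusted p = 0.927). The relation of the overexpression strain with the strain labelled trxB2 mutant was r = 0.55 from arrays 2 and 4, 0.71 from slide 1 with array 4, and 0.71 to 0.77 with an array left out. Slide 1 with array 4 is the same computation as leaving out array 3. With any other array left out, both differences share arrays, which adds to r. The other relations ranged from -0.21 to 0.22 and from 0 to 0.23, with 0.32 from arrays 1 and 3. The cause was not tested for these changes. No paired analysis was possible because each group held 1 array. As for signal over background, the counts depend on the correction, as given above, and 28 locus spots were dim in both channels of all 4 arrays.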

Other observations

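The relations across loci in this part were planned, while its other tests, and what each explanation predicts, were set after the results were seen. Loci that differed from the WT in the same direction in all 3 other strains were few. Of 8 loci that fell in each of them, lp_RNA01 stood at -0.82 ± 0.071 on the log2 scale in the strain labelled trxB1 mutant, at -1.41 ± 0.082 in the overexpression strain and at -1.52 ± 0.071 in the strain labelled trxB2 mutant, and lp_RNA02 at -0.98 ± 0.078, -0.70 ± 0.09 and -0.67 ± 0.078. The only locus that rose in all 3, lp_0927, stood at 0.65, 0.68 and 0.61. The 13 loci with tRNA in their IDs had medians of -0.26, -0.33 and -0.34 in these strains, with 2, 2 and 5 of them called lower and 0 higher. These loci were chosen after their values were seen, and since each difference is taken against the same WT channels, what is particular to the WT samples enters all 3.

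Loci next to trxB2 in tag order were examined because lp_2585 itself did not pass the test. With marked spots kept, lp_2584 was higher than the WT by 0.67 ± 0.075 in the strain labelled trxB2 mutant and lp_2586 by 0.43 ± 0.075, the latter short of 1.5-fold. The 3 probes of lp_2584 gave 0.65, 0.49 and 0.87 there, with limma adjusted p of 0.0015, 0.0049 and 0.00011, and those of lp_2586 gave 0.74, 0.24 and 0.32. Probe 2 of lp_2584 was marked on 3 arrays, and these values are not calls of the main fit. In the strain labelled trxB1 mutant the loci stood at 0.11 ± 0.075 and 0.13 ± 0.075.

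The trxB1 signal was not lower in the strain labelled trxB1 mutant. If the labels of both mutant strains were exchanged, trxB2 signal would be lower in the strain labelled trxB1 mutant and trxB1 signal in the strain labelled trxB2 mutant. Of the 3 trxB1 probes, 1 was lower in the strain labelled trxB2 mutant at a limma adjusted p under 0.05 and 1 higher (0.42, limma adjusted p = 0.031). The lower one, probe 3, was marked on 0 arrays, and its 2 spots gave -1.03 and -0.97. The higher one, probe 2, was marked poor on array 3, as was probe 1 (-0.11). Of the 3 trxB2 probes, 0 were lower in the strain labelled trxB1 mutant. In the strain labelled trxB2 mutant 1 of them was lower (-0.37, limma adjusted p = 0.013) and 1 higher (0.30, limma adjusted p = 0.043). Probes outside the disrupted part are another candidate explanation, and 0 of the 3 trxB1 probes lay below the WT in the strain labelled trxB1 mutant. Without probe positions and the sites of the disruptions, neither can be told apart from a strain in which the gene is intact.

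The overexpression strain and the strain labelled trxB2 mutant changed alike against the WT. The shared WT channels are argued against as the whole cause by arrays 2 and 4, which share no strain and correlated at r = 0.55 across loci, where 100 simulations without strain effects reached at most 0.05. A dye effect of opposite sign on the slides would give the strain labelled trxB1 mutant the same profile at a smaller size. That strain and the overexpression strain had r = -0.08 and a covariance of -0.00425. Simulations without strain effects gave r of at least 0.55 and a mean covariance of 0.00313. These values argue against such a dye effect as the whole cause. Cultures grown or harvested in 2 batches may also give such a pattern, and with 0 samples whose labels name a batch they cannot be told apart from a difference between the strains. A shared response of these strains stays open and untested.

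The 3 loci of plasmid 2 rose in the overexpression strain by a mean of 1.91 on the log2 scale. A rise of all native plasmids by this amount is argued against by the 41 loci of plasmids 1 and 3, whose median was 0.24. Its bootstrap SD over loci was 0.04, which treats loci as independent and holds no error between cultures. Of these loci 38 lie on plasmid 3, and the 3 of plasmid 1 lay between 0.06 and 0.66. A candidate explanation is the overexpression vector binding these probes, and 9 of the 9 plasmid 2 probes rose by at least 1.5-fold, which a match of the vector to all of them would give and a higher copy number or expression of plasmid 2 would give as well. These cannot be told apart, since vector and probe sequences were not used here, and no biological explanation was tested.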
